A study of Mus musculus with 8 samples.

How the data were processed

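Total RNA was taken from the liver of 8 male mice of the C3HeB/FeJ strain, all 21 weeks old, and each sample was hybridised to 1 Illumina bead array, on which every gene is read by 1 or more probes attached to beads. Per the labels' protocols, RNA was extracted with Trizol, cleaned on RNeasy columns, checked on a gel and amplified as biotin-labelled cRNA. Arrays were grouped by the genotype label, 4 wild type and 4 heterozygous for a Jag1 allele that replaces a lysine codon with a stop codon. The sample titles shorten the second group to "hom", whereas the genotype label and the design text both say heterozygous, and the groups follow these. Each sample carries its own mouse number, so the replicates are separate animals. The labels name no chip, hybridisation day or other batch, so a batch effect could not be tested.

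The authors deposited, per the file headers, a table of non-normalized signal intensity for 25697 probes on each of the 8 arrays, with a detection p-value beside each intensity. Per the submitters' processing notes the signals came from GenomeStudio 2011.1. A further deposited table holds processed intensity values of the same arrays on a linear scale. Its medians were 8.98, 8.96, 8.97 and 8.99 on the wild-type arrays and 8.97, 8.96, 8.97 and 8.97 on the heterozygous arrays, and 8442 to 8454 of its values per array lay below 0. Within each array its ranks differed from those of the non-normalized signals by at most 1.5 ranks, which ties every column to its array. The background subtraction and the normalization behind that table are not given in the sources used here.

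The non-normalized signals were used for all results. Background was corrected with the nec function of limma 3.58.1 in R 4.3.3, which infers the mean and spread of the negative controls from the detection p-values, and an offset of 16 was added. The arrays were then quantile normalized and the values taken as log2. A probe was tested if its detection p-value was under 0.05 on at least 4 of the 8 arrays, whatever their group, which left 11412 probes. Low signals are compressed by the offset, so fold changes of dim probes are understated. Probes were named from GEO's platform annotation. It gave 1 symbol to 23978 probes, several to 0 and none to 1719, and an update through the Entrez identifiers of the GRCm38.p6 annotation changed 0 symbols. Of the tested probes 10758 were named, for 7960 genes, and 654 were not. No genome coordinates are given, because the files name no genome build.

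Heterozygous and wild-type arrays were compared with limma's lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over the tested probes and a threshold of 0.05. Errors of log2 fold changes are standard errors of this fit, and errors of group means are SDs over 4 arrays. For gene lists, 1 probe stood for each gene, the one with the highest mean log2 signal over all arrays among those tested. This choice concerned 2048 genes with several tested probes, and 18 genes had probes with an unadjusted p under 0.05 in opposite directions. The 34 lists cover Notch signalling, bile duct cells, bile acids, lipid, glucose and drug metabolism, other cell types in or beside the liver, inflammation, stress, the clock and the cell cycle, ribosomal and mitochondrial genes, and hepatocyte zones. Each list with at least 5 measured genes was tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the 32 lists tested. The lists hold genes in common, such as Dusp1 and Cdh1, so they are not independent of each other. Members were also adjusted over the list alone. A single value was compared with an exact two-sided permutation test over the 70 assignments of the 8 arrays, whose smallest p is 0.0286.

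The groups, the tests, the lists, the alternatives except the clock covariate, and the rule for named genes were set before the data were examined. The rule names Jag1 and Notch2, then, per direction, the genes past the threshold whose groups do not overlap, filled up to 8 by the smallest unadjusted p. For each list it names up to 4 members past the threshold over all probes or over the list alone, the largest first, or else the 2 with the smallest unadjusted p. Zfp36, Mcl1, Cish and the genes of the clock and growth hormone relations, and genes called when an array was left out, were named after their values were seen. The alternatives were no background correction, an offset of 50, median scaling, no filter, a filter of detection p-value under 0.01 on all 8 arrays, the processed table, the replicate number as a block, leaving out each array, array weights, a trended robust prior, an adjusted p under 0.10, the mean of a gene's probes, an estimated correlation in camera, and fry. A BeadChip block was planned and not run, because no chip is named.

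The steps were tested on simulated data made from the means and spread of the 11412 tested probes in 4 arrays against 4. limma called 37 of 67 probes changed by 0.5 log2 units, 64 of 67 changed by 1 and 65 of 66 changed by 2, all in the right direction, with 5 false calls. The noise was drawn independently for each probe, with equal spread in both groups, and many probes were changed at once. The shares called therefore need not hold for the real arrays. With independent noise, camera called a list of the 7960 genes shifted by -0.3 log2 units and 0 of the others. Bead arrays give no read depth, and the number of arrays limits the precision.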

Results

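Liver RNA of 4 male mice heterozygous for a nonsense allele of Jag1 and of 4 male wild-type mice was profiled on bead arrays, 1 per mouse. Jag1 encodes a ligand of the Notch receptors, and the series presents these mice as a model of Alagille syndrome, an inherited disorder with a paucity of bile ducts that mostly follows loss of a copy of JAG1. The comparison therefore asks which liver transcripts differ between adult heterozygous and wild-type mice. Mean signals per array ranged from 422 to 488, and 11022 to 11873 of the 25697 probes had a detection p under 0.05. Pearson correlations between pairs of arrays, over the tested probes, ranged from 0.985 to 0.994. The first principal component held 30.3% of the variance and the second 16.1%. Heterozygous replicate 4 stood apart on the first, at 24.3, with the other arrays between -12.3 and 6.90.

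The mutated gene itself could not be measured in these samples. The Jag1 probe was not well above background on any array, with signals of 111, 119, 123 and 123 in wild type and 111, 112, 120 and 113 in heterozygous liver, and detection p-values from 0.301 to 0.895. Its normalized log2 signal was 4.41 ± 0.07 (SD, n = 4) in wild type and 4.39 ± 0.08 (SD, n = 4) in heterozygous mice (exact permutation test, two-sided, p = 0.714). No fold is given for values at background, and where the probe lies relative to the stop codon is not known here, so the genotype labels were not checked by this gene. Notch2, a receptor of Jag1, was read by 2 probes that also passed the detection threshold on 0 of 8 arrays.

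Krt23, a keratin gene counted here among the bile duct markers, fell in heterozygous liver. Its log2 signal was 6.99 ± 0.29 (SD, n = 4) in wild type and 5.63 ± 0.07 (SD, n = 4) in heterozygous mice, 2.56-fold lower, and 4 of 4 heterozygous arrays lay below the lowest wild-type array. The limma log2 fold change was -1.36 ± 0.13 (SE; adjusted p = 0.0104). Of the 11412 probes tested with limma, 0 were higher and 1 was lower past the threshold. At an unadjusted p under 0.05 there were 600 higher and 679 lower probes, 1279 in all where 571 would be expected with no effect. The groups did not overlap for 713 probes, 6.25% of those tested, against 2.86% by chance. The Krt23 call ended without wild-type replicate 4 (log2 fold change -1.30, adjusted p = 0.0735) and without heterozygous replicate 3 (-1.33, 0.0903). It also ended without the detection filter (-1.36, 0.0718) and with the replicate number as a block (-1.36, 0.0553). In these settings the fold hardly moved. Krt23 lost its call without background correction too (-0.59, 0.0540), where its fold shrank. Its adjusted p ranged from 0.000371 to 0.0903 over all alternatives, and the count of probes rose to 7 without heterozygous replicate 1 and to 2 without heterozygous replicate 2.

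**Figure D1:**
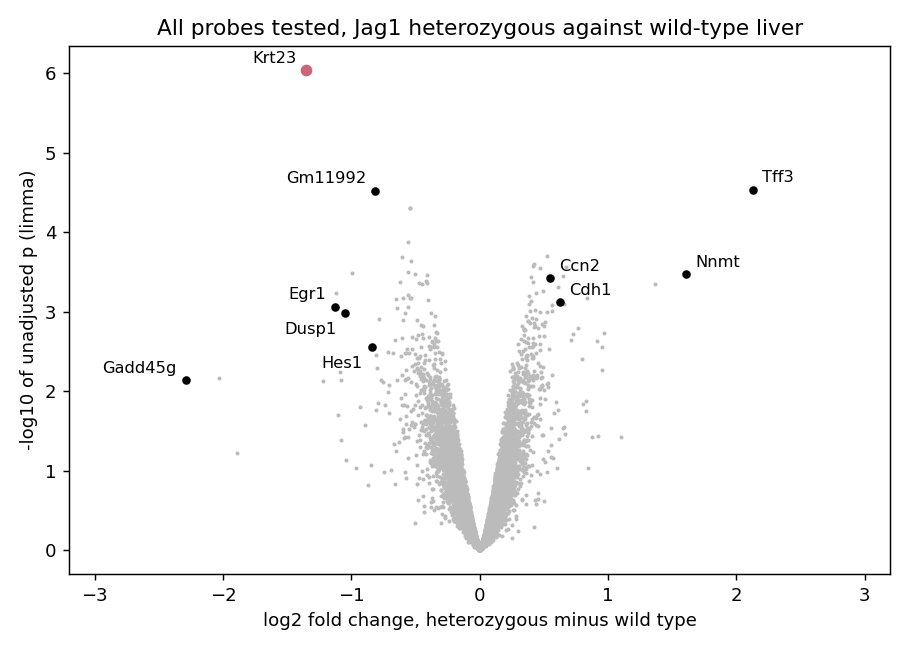
Each point is 1 of the 11412 probes tested, with the log2 fold change (heterozygous minus wild type) on the horizontal axis and -log10 of the unadjusted limma p on the vertical axis; named genes are in black and the probe past the threshold is in red. Krt23, at a log2 fold change of -1.36, is the probe past the threshold, and Tff3 at 2.13 and Nnmt at 1.61 lie farthest to the right among the named genes.

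The largest differences on the higher side did not pass the threshold. Tff3, which encodes a trefoil peptide of mucous epithelia, had a log2 signal of 5.49 ± 0.37 (SD, n = 4) in wild type and 7.62 ± 0.69 (SD, n = 4) in heterozygous liver, a log2 fold change of 2.13 ± 0.30 (SE; limma adjusted p = 0.114). It passed without heterozygous replicate 2 (log2 fold change 2.42, adjusted p = 0.0318; range over all alternatives 0.0318 to 0.3305). Nnmt, encoding nicotinamide N-methyltransferase, had a log2 fold change of 1.61 ± 0.31 (SE; limma adjusted p = 0.182), and its other probe gave 1.36. By the brightest probe of each gene, the other genes with the smallest p on this side were Kpnb1 (importin beta, log2 fold change 0.42), Slc27a1 (a fatty acid transporter, 0.42), Mlkl (the effector of necroptosis, 0.47), Cpne8 (0.65), Zfc3h1 (0.40) and Ccn2 (a secreted matrix-associated protein, 0.55). By the same probes, on the lower side they were, after Krt23, Gm11992 (-0.82), Aqp4 (a water channel, -0.61), Stam (-0.56), Mkx (a homeobox gene, -0.999), Rbm10 (-0.42), Inpp5j (-0.41) and Cbx5 (heterochromatin protein 1 alpha, -0.45). For all of these the 4 heterozygous arrays lay on 1 side of the 4 wild-type arrays, and their limma adjusted p-values lay between 0.114 and 0.182. Several are dim: Gm11992 and Aqp4 passed the detection threshold on 4 arrays and Stam, Mkx, Rbm10, Inpp5j and Slc27a1 on 5. Other probes of Stam and Rbm10 gave -0.24 and -0.09. Dimmer probes of several other genes, among them Insig1 (0.53) and Rtn4 (-0.56), also had p-values in this range.

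**Figure D2:**
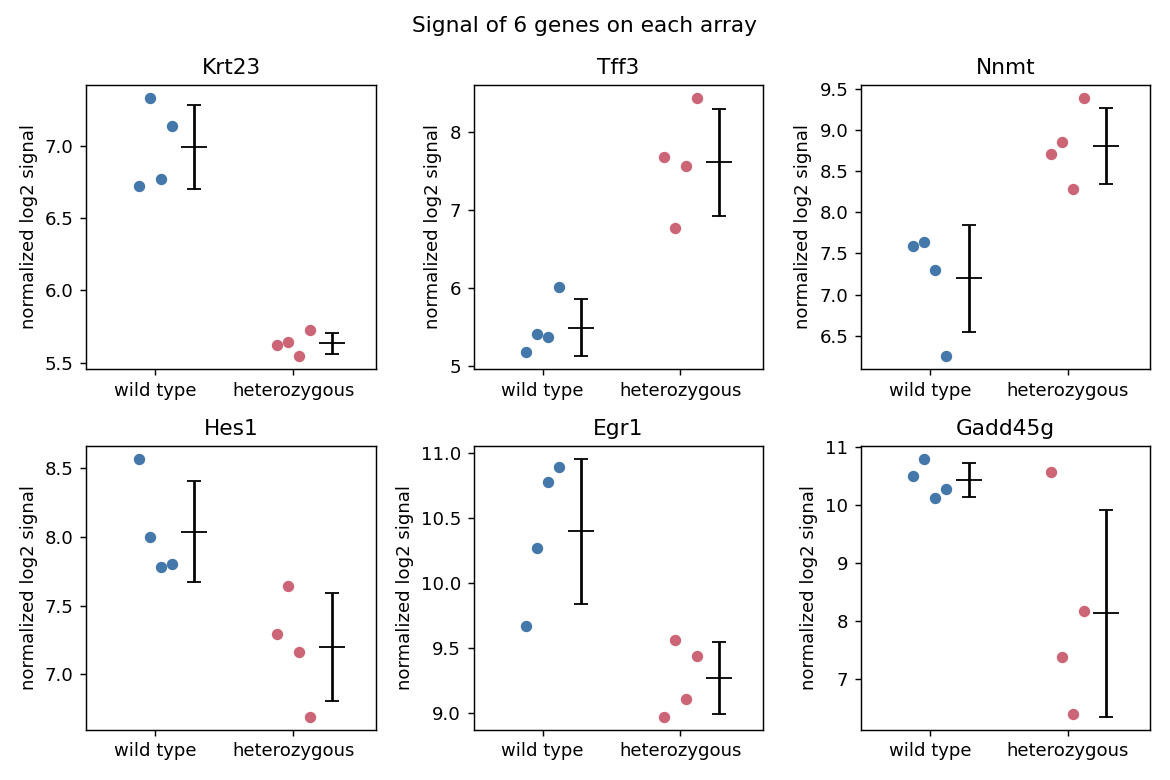
Normalized log2 signal of 6 genes on each array, as points for the 4 wild-type (blue) and 4 heterozygous (red) mice, with the mean and SD of each group beside them. Krt23 lay between 6.72 and 7.33 in wild type and between 5.55 and 5.73 in heterozygous mice, and for Gadd45g 1 heterozygous array, at 10.6, lay among the wild-type arrays. The vertical axes do not start at 0 and differ between genes.

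Genes of the Notch pathway gave no call over all probes. Among the 11 measured Notch targets, Hes1, a transcriptional repressor induced by Notch, was 8.04 ± 0.37 (SD, n = 4) in wild type and 7.20 ± 0.40 (SD, n = 4) in heterozygous liver, a log2 fold change of -0.84 ± 0.22 (SE; limma adjusted p = 0.256). Hes1 was the 1 member past the threshold when adjusted over the list alone (adjusted p = 0.0302). The targets as a list had a median log2 fold change of 0.06 and 0 members past the threshold over all probes (camera adjusted p = 0.581). Of 20 measured ligands, receptors and processing genes, 0 passed over all probes or adjusted over the list alone, and the median was 0.06 (camera adjusted p = 0.261). The smallest p-values among them were those of Dtx3 (log2 fold change 0.37) and Numb (-0.32).

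Of the 13 measured bile duct genes, Krt23 fell, and 1 higher and 1 lower gene passed when adjusted over the list alone. The higher gene was Cdh1, encoding E-cadherin of epithelial junctions, with a log2 fold change of 0.62 ± 0.13 (SE; limma adjusted p = 0.204, 0.00489 over the list alone). The list had a median of -0.01 (camera adjusted p = 0.927). Bile acid synthesis (16 genes, median 0.03, camera adjusted p = 0.927) had 0 members past the threshold by either adjustment, with Cyp7b1 at a log2 fold change of 0.25 and Cyp39a1 at -0.30. Bile transport (15 genes, median -0.04, camera adjusted p = 0.352) likewise had 0, with the copper transporter Atp7b at -0.30 and the uptake transporter Slco1b2 at -0.54. Among 17 liver transcription factors and nuclear receptors (median -0.05, camera adjusted p = 0.783), Rxrb was at 0.30 and Foxa2 at -0.59, and 0 passed by either adjustment.

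Among the 32 lists tested with camera at the preset correlation, 4 fell relative to the other genes and 0 rose: early response genes, fatty acid oxidation, fatty acid synthesis, and macrophage and Kupffer cell markers. The shifts were small, with median log2 fold changes of -0.14, -0.12, -0.11 and -0.12, and adjusted p-values of 0.01001, 0.01001, 0.0103 and 0.0143. With an estimated correlation 0 lists passed, with adjusted p = 0.796 for early response genes, p = 0.796 for both lipid lists and p = 0.807 for the macrophage list, and 0 passed with fry. Without wild-type replicate 2, 0 lists passed, with adjusted p-values of the 4 from 0.0503 to 0.0842. Without heterozygous replicate 4, which stood apart on the first principal component, the early response (0.0840) and fatty acid synthesis (0.258) lists did not pass, and without heterozygous replicate 3 the oxidation (0.0670) and macrophage (0.469) lists did not. The macrophage list also ended without wild-type replicate 1 (0.109) and without the detection filter (0.0787), and the early response list without the filter (0.0984). The medians moved over 1.5 times, for early response genes to -0.25 without wild-type replicate 3, -0.21 without heterozygous replicate 2, and -0.06 both without background correction and without the filter. For fatty acid oxidation they moved to -0.05 without wild-type replicate 2, -0.19 without heterozygous replicate 2, -0.06 without heterozygous replicate 3, -0.07 without background correction, -0.08 both with offset 50 and without the filter, and -0.18 with the mean of probes. For fatty acid synthesis they moved to -0.18 without heterozygous replicate 3 and -0.06 without heterozygous replicate 4, and for macrophage markers to -0.03 without heterozygous replicate 3, -0.20 without heterozygous replicate 4, -0.05 without background correction and -0.06 without the filter. Other lists passed only with an array left out: gluconeogenesis, higher (0.0357), and endoplasmic reticulum stress, lower (0.0152), without wild-type replicate 1, female-biased genes, lower (0.0154), without wild-type replicate 3, erythroid markers, lower (0.0410), without wild-type replicate 4, and neutrophil markers, lower (0.0177), without heterozygous replicate 2.

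The early response genes are transcribed within minutes of a stimulus. Of 14 measured, 10 were below 0 and 0 passed over all probes, while 5 lower and 1 higher passed when adjusted over the list alone. Egr1, a zinc finger transcription factor, was 10.4 ± 0.56 (SD, n = 4) in wild type and 9.27 ± 0.27 (SD, n = 4) in heterozygous liver, a log2 fold change of -1.13 ± 0.24 (SE; limma adjusted p = 0.213). Gadd45g (-2.29), the phosphatase gene Dusp1 (-1.05), Junb (-0.81) and Zfp36 (-0.79) were the other lower members and Mcl1 (0.31) the higher one. Gadd45g rested on 3 of the 4 heterozygous arrays, with an SD of 1.78 over them against 0.29 in wild type. Without heterozygous replicate 1, Gadd45g (limma adjusted p = 0.0155), Dusp1 (0.0131) and Foxa2 (0.0284) passed the threshold over all probes, and their highest values over all alternatives were 0.606, 0.508 and 0.609.

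Of the lipid genes 0 passed over all probes, and neither lipid list was called with the estimated correlation. Of 31 fatty acid oxidation genes, 24 were below 0, and Acadl, encoding the long-chain acyl-CoA dehydrogenase of mitochondria, was the 1 past the threshold over the list alone (log2 fold change -0.49, adjusted p = 0.0393). Its other probe gave 0.13. Of 24 fatty acid synthesis genes, 18 were below 0 and 0 passed by either adjustment. Pklr, encoding liver pyruvate kinase, was at -0.48 and Pnpla5 at -0.57. Cholesterol synthesis (18 genes, median -0.04, camera adjusted p = 0.345) had 0 past by either adjustment, with Nsdhl at -0.34. The probes of Insig1, a sterol-regulated gene, disagreed: the brightest gave -0.45, the others -0.37 and 0.53.

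None of the glucose, drug metabolism and other hepatocyte lists was called. In the gluconeogenesis and glucocorticoid list 19 of 26 measured genes were above 0, with a median of 0.10 (camera adjusted p = 0.118). Adjusted over the list alone, Irs2, an insulin receptor substrate (log2 fold change 0.83), G6pc, the catalytic subunit of glucose-6-phosphatase (0.96), and Agxt (0.34) were higher and Dusp1 was lower, with 0 past over all probes. Among 21 pericentral genes (median 0.09, camera adjusted p = 0.212), Glul, encoding glutamine synthetase (0.52), and Oat, encoding ornithine aminotransferase (0.42), passed over the list alone. Among 24 periportal genes (median 0.07, camera adjusted p = 0.188) Cdh1 did. Secreted hepatocyte proteins (34 genes, median 0.04, camera adjusted p = 0.345) had 0 past by either adjustment, with the clotting factor gene F7 at 0.23 and Igfbp2 at 0.66. Drug metabolism (36 genes, median 0.00, camera adjusted p = 0.472), with Cyp2b10 at -0.52 and Cyp2c50 at 0.18, and oxidative stress (19 genes, median 0.00, camera adjusted p = 0.944), with Txn1 at 0.20 and Txnrd1 at 0.35, had 0 as well. Of the sex-biased lists, the male-biased one (21 genes, median 0.05, camera adjusted p = 0.345) had 0 past, with Gadd45g at -2.29 and Egfr at 0.65. Other probes of Egfr gave 0.31, 0.30 and 0.14. The female-biased list (9 genes, median -0.43, camera adjusted p = 0.202) had Rtn4, a reticulon, past over the list alone (-0.61, adjusted p = 0.0326).

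**Figure D3:**
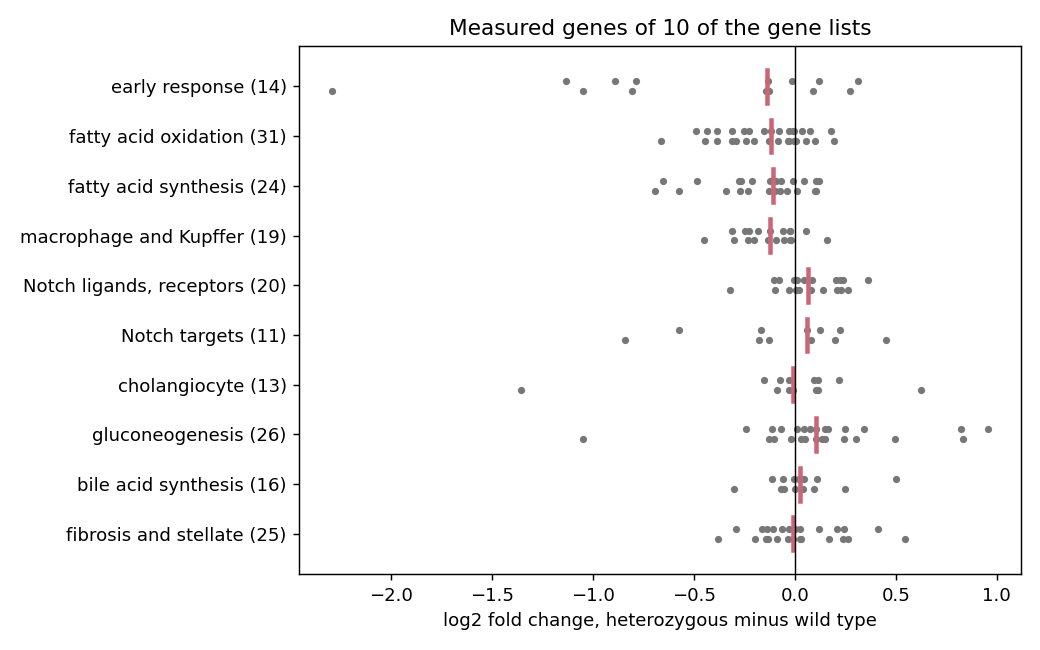
Each point is 1 measured gene of a list, placed by its log2 fold change (heterozygous minus wild type) on the horizontal axis, with the number of measured genes in brackets and the list's median as a red bar. The medians of the upper 4 lists lay between -0.14 and -0.11, and in the bile duct list Krt23 lay at -1.36 while the median was -0.01.

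Markers of other cell types were near 0 or slightly below it. In the macrophage list 17 of 19 measured genes were below 0 and 0 passed by either adjustment; the Kupffer cell genes Fcna and Vsig4 were at -0.45 and -0.30. Lymphocyte markers (9 genes, median -0.10, camera adjusted p = 0.352; Prf1 0.21, Coro1a -0.21), neutrophil markers (5 genes, median -0.11, camera adjusted p = 0.190; Cxcl1 -0.58, S100a8 -0.40), endothelial markers (32 genes, median -0.01, camera adjusted p = 0.381; Vwf 0.36, Flt4 -0.25) and erythroid markers (7 genes, median -0.21, camera adjusted p = 0.166; Hba-a1 -0.45, Hbb-b2 -0.43) had 0 past by either adjustment. In the fibrosis and stellate cell list (25 genes, median -0.01, camera adjusted p = 0.927) Ccn2 passed over the list alone (log2 fold change 0.55, adjusted p = 0.00936). The pancreatic and adipose lists had 3 measured genes each and were not tested as lists, with medians of 0.07 and 0.07; Ctrl was at 0.21, Amy2a5 at -0.22, Lpl at 0.82 and Car3 at -0.11.

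Inflammation, stress and growth lists gave no call. In the interferon list (35 genes, median -0.00, camera adjusted p = 0.927) Ifi27 passed over the list alone (log2 fold change 0.39, adjusted p = 0.0341), and its other probe gave 0.47. None of the following had a member past by either adjustment: acute phase genes (27 genes, median 0.07, camera adjusted p = 0.212; Itih3 0.28, Mt2 0.83), cell cycle genes (15 genes, median 0.04, camera adjusted p = 0.472; Cdt1 0.25, Pcna 0.21), endoplasmic reticulum stress genes (24 genes, median -0.06, camera adjusted p = 0.207; Edem1 -0.50, Asns 0.67) and heat shock genes (16 genes, median 0.05, camera adjusted p = 0.489; Cryab -0.21, Hspb1 0.42). The same held for clock genes (17 genes, median 0.02, camera adjusted p = 0.512; Rora -0.19, Nr1d1 -0.20), ribosomal protein genes (52 genes, median 0.04, camera adjusted p = 0.394; Rpl27a 0.25, Rpl5 0.19) and oxidative phosphorylation genes (67 genes, median -0.03, camera adjusted p = 0.352; Ndufb4 0.36, Sdhd 0.29). The median and the camera direction had opposite signs for the Notch target, drug metabolism, oxidative stress and clock lists, and the median and the mean for those 4, the male-biased list and the fibrosis list.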

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

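Among 160 sets of 4 values, 1 set per named gene or array measure and group, 7 held an array far from the other 3, where chance alone puts about 1 in 20, or 8. In wild type, replicate 2 had log2 signals of 5.56 for Aqp4, against 5.15 to 5.18 on the other arrays, 7.03 for Cdh1, against 7.21 to 7.22, and 14.1 for Car3, against 13.9. Wild-type replicate 4 had 5.02 for Ctrl, a pancreatic protease, against 4.82 to 4.83. Heterozygous replicate 3 had 4.80 for the same gene, against 5.16 to 5.19. Heterozygous replicate 4 had 8.49 for the brightest Insig1 probe, against 9.05 to 9.12, and 9.17 for the ribosomal protein gene Rpl27a, against 8.82 to 8.85. Of the 7 values, 3 came from wild-type replicate 2 and 2 from heterozygous replicate 4.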

How the results depend on the processing

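The clock covariate (each array's Dbp minus Arntl difference) was chosen after the data were seen. The count of probes past the threshold, 1, fell to 0 without background correction, to 0 without the filter and to 0 with the replicate block, and the count of list members past it over all probes, 1, fell to 0 under the same 3 settings; it ranged from 0 to 7 for probes and from 0 to 4 for members when each array was left out. With the block Krt23 kept its log2 fold change of -1.36 at an adjusted p of 0.0553, with 3 degrees of freedom fewer. Whether the replicate numbers pair the arrays is not settled. Deviations from the group means correlated at -0.07, 0.13, 0.10 and 0.08 for the 4 numbers. Of the 8 arrays, 4 correlated best with their own number among the 4 arrays of the other group. With the block, the probes at an unadjusted limma p under 0.05 rose from 1279 to 1417. The count of lists past the threshold, 4, became 2 without the filter, 0 with an estimated correlation and 0 with fry. It ranged from 0 to 5 when each array was left out, with 0 without wild-type replicate 2. At an unadjusted p under 0.05 there was 1 list with the estimated correlation and there were 2 with fry. These lists were not among the 4. They were gluconeogenesis in both settings and secreted hepatocyte proteins with fry, each in the higher direction. The estimated correlation can raise p even where the estimate lies below the preset 0.01. For gluconeogenesis the estimate was -0.0101, yet the camera p rose from 0.0184 to 0.0388. For the liver transcription factors, at -0.0221, it fell slightly, from 0.660 to 0.653. A call lost in this setting therefore need not come from the size of the estimate alone. For the early response, oxidation, synthesis and macrophage lists the estimates were 0.15, 0.11, 0.26 and 0.45. Leaving out arrays lowers their number, and for the other settings the cause was not tested. Offset 50, median scaling, the filter on all 8 arrays, the processed table, array weights, the trended prior, an adjusted p under 0.10, the mean of probes and the clock covariate each gave 1 probe or list member and 4 lists wherever they apply. Over 77 named genes, 1434 of 1443 values under an alternative kept their direction and side of the threshold, 5 were weaker and 4 stronger, and 0 reversed. All 5 weaker values were those of Krt23, the 1 gene past the threshold. The other named genes had not passed it, so most of their values could only stay on the same side, and the pooled count says little about robustness. For the 4 lists 65 of 84 kept both, 19 were weaker and 0 reversed. Jag1 has no alternative values, because its probe was below the detection threshold on 8 of 8 arrays, and a BeadChip block was not run. Precision is limited by signal over background: the median tested probe was 2.18 to 2.41 times the background signal on each array.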

Other observations

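The tests of the clock covariate, tissue carried over, bile duct cells, the span of Cish and the shared clock phase were chosen only after the results they bear on had been seen, and the estimated correlation, an alternative set before the data were examined, was taken as a test of co-regulation only then. The genes in the next paragraph were chosen after their values were seen.

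Some clock genes and Cish varied between mice of 1 genotype. Dbp, a clock output transcription factor, ran from 10.4 to 11.8 log2 units in wild type and from 8.32 to 11.7 in heterozygous mice, with heterozygous replicate 4 lowest. Arntl, which encodes BMAL1 and peaks in the opposite phase, was highest in that mouse, at 7.39. Within groups Dbp and Arntl were opposed over the 8 arrays (Pearson r = -0.87, exact permutation p = 0.00347; Spearman rho = -0.95, exact permutation p = 0.00347; adjusted p = 0.0278 over 8 relations), and r was -0.90 without the 2 arrays farthest from the median. A known phase was taken for 9 of the other measured clock genes, while others, such as Rora, were left out. All 9 went with Dbp or with Arntl as known for them. Within-group permutations often reach that count (exact p = 0.227) because these genes move together. Their mean r with the Dbp minus Arntl difference, signed by the known direction and tested after that count was seen, was 0.811 (exact one-sided permutation p = 0.00347), which is consistent with a clock phase that differs between mice. Whether the mice differed in phase or in the time of dissection was not tested. Cish, a target of growth hormone signalling, read 10.9, 6.54, 5.96 and 7.93 on heterozygous arrays 1 to 4, against 8.90 to 10.7 in wild type.

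Krt23 fell in heterozygous liver, and Tff3 and Nnmt had the largest log2 fold changes above 0 among the named genes without passing the threshold. Of the 35 splits of the arrays, 1, the real one, called a probe and the highest of the others called 0; 1 of 35 is the smallest share the splits can give, so chance is argued against for the count of 1 no further than that; at an unadjusted p under 0.05, 2 splits reached the real 1279, the other with 1309 after wild-type replicate 4 and heterozygous replicate 1 changed places. Gut, stomach or pancreas tissue carried over is argued against in either group. Of 33 such markers 25 were detected on 0 arrays. In heterozygous mice 0 were over 1 log2 unit higher (as Tff3 and Nnmt would need) and 0 over 1 lower (as Krt23 would need). The 5 detected on 4 of 4 arrays of each group differed by -0.45 (Apoa4) to 0.18 (a probe of Lgals4). Of these, Apoa4 and Cela1 were bright in both groups, at 11.4 and 10.8 log2 units in wild type. Such markers could show little of a small carry-over, so the argument rests mainly on the 25 that were not detected. With the clock covariate Krt23, Tff3 and Nnmt kept at least 0.905 of their log2 fold change. The Dbp minus Arntl difference was 4.20 ± 1.24 (SD, n = 4) in wild type and 3.69 ± 1.92 (SD, n = 4) in heterozygous mice. A covariate this close between groups could remove little. The fit argues only against a group shift in that difference as the cause. A lower share of bile duct cells may underlie Krt23 and stays open. The other 12 measured genes of the list had a median of 0.0442, but hepatocytes make several of them. The 2 that they make little of, Krt7 (log2 fold change -0.03 ± 0.14, SE) and Cldn7 (0.12 ± 0.16, SE), did not fall with Krt23. Both were below 6 log2 units, where the offset compresses folds, so they do not decide the question. An effect of the Jag1 genotype itself also stays open, as untested.

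The early response genes and 3 other lists passed the threshold as lower with the preset correlation and did not with an estimated one. Of the 35 splits, 26 called at least as many lists as the real 4, with 12 the highest of the others and 8 splits calling the early response list, so chance cannot be excluded for the list calls. Co-regulation beyond the preset correlation may account for the early response call, but the test cannot decide this. With an estimated correlation, 0.15 for this list, its camera p was 0.0782 (adjusted p = 0.796). That setting also raised the p of the gluconeogenesis list, whose estimate lay below the preset. With the clock covariate the early response median was -0.13 (camera at the preset correlation, adjusted p = 0.0319). The Dbp minus Arntl difference was 4.20 ± 1.24 (SD, n = 4) in wild type and 3.69 ± 1.92 (SD, n = 4) in heterozygous mice. A covariate this close between groups could move the median little. The fit argues only against a group shift in that difference as the whole cause. It used a single slope, although the list mean followed the difference at r = -0.21 in wild type and 0.52 in heterozygous mice. Whether heterozygous replicate 4 carries the early response call stays open: without it the median was -0.0943 and the adjusted p 0.0840, the call also ended without wild-type replicate 2 (0.0503), and it held without each other array (0.000478 to 0.0303).

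Cish and Gadd45g differed between heterozygous mice by far more than between wild-type mice. Over the 3 heterozygous arrays whose Dbp minus Arntl difference lay inside the wild-type range, Cish spanned 4.91 log2 units against 1.76 in wild type. Gadd45g spanned 4.17 against 0.67. These spans argue against that difference as the whole cause of the spread in heterozygous mice. Cish followed the difference in wild type (Pearson r = 0.997) but not in heterozygous mice (r = -0.02). Within groups r was 0.18 (exact permutation p = 0.767). A part played by the clock stays open, because the difference only stands in for the phase. The state of growth hormone signalling through STAT5 in each mouse stays open as a hypothesis: Bcl6, which it represses, opposed Cish within groups (Pearson r = -0.77, exact permutation p = 0.0972; rho = -0.83, exact permutation p = 0.0556; r = -0.74 without the 2 farthest arrays; adjusted p = 0.259 over 8 relations). Socs2, which it induces, gave Pearson r = 0.32 (exact permutation p = 0.569; rho = 0.14, exact permutation p = 0.792; r = 0.01 without the 2 farthest; adjusted p = 0.651), so the test does not decide.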
